A study of Arabidopsis thaliana with 15 samples.

How the data were processed

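RNA of the aerial part of Col-0 seedlings grown on plates was profiled after 4 days of stratification and 4 days in darkness at 22 °C (Dark), and after 4 hours more in white light at 100 µmol per square metre and second (L4h) or in darkness (D4h), per the labels. Total RNA of all 3 conditions and polysome-bound RNA of Dark and L4h were sequenced as 15 libraries, 3 per group. The labels number 3 replicates per group, where the series text speaks of 2, and there is no polysome D4h group. Extraction used a CTAB buffer and lithium chloride per the labels. Kit, strand, aligner and counting tool are not given, and the submitters' processing notes name genome build TAIR10.

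The authors deposited 1 table per library with 33323 genes each. Read numbers were deposited as estimated counts (expected counts of the authors' counting tool), not normalized, with whole values in 84.4% to 87.2% of genes (tolerance 1e-06), and were rounded for testing. RPKM values were computed by the authors per kilobase of the listed gene length and per total reads, a total that exceeded the listed sum by 0.971% to 4.16%. Gene length in kilobases was deposited by the authors beside them and is the same in every file. Libraries held 60.8 to 100.9 M reads in listed genes. No plastid or mitochondrial gene is listed. A reference annotation supplied symbols and biotypes for 32835 genes. Reads of near-identical copies and of genes that overlap on either strand cannot be assigned with certainty, since the strand is not known.

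Counts were fitted with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr with a minimum count of 10, quasi-likelihood F tests and Benjamini-Hochberg adjusted p under 0.05, with a second count at a log2 change of at least 1. The 9 total RNA libraries were fitted together for L4h against Dark, D4h against Dark and L4h against D4h, the 6 polysome libraries for L4h against Dark, and the 12 libraries of Dark and L4h for polysome-bound against total RNA and for the interaction of light with the kind of RNA. CPM levels are scaled within each of these fits, so a library's level differs a little between comparisons, and over all 15 libraries for figures and for values of single libraries. Log2 changes of genes are those of edgeR at its default, and their SE is the change over the root of F. Log2 CPM for components and list tests carries a prior count of 2. A ratio over a group with no read is given as a floor of 3 counts over the group. Groups were called non-overlapping where all libraries of one lay above all of the other. The least p of an exact permutation of 3 against 3 is 0.1, so no permutation test was used for genes.

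The design, the alternatives, the rule for naming genes and 26 gene lists (496 genes, all found) were fixed before the data were examined. Named genes are the 6 with the largest rise and the 6 with the largest fall (adjusted p under 0.05, at least 10 CPM in the higher group, groups not overlapping), the first 2 tested members of each list, up to 2 further members with the largest change past the threshold, and other members as examples. Each was tested with camera (limma 3.58.1) at its preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison, and its genes were adjusted a second time over the list alone.

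Alternatives were DESeq2 1.42.0, RLE scaling, no filter, a filter of RPKM of at least 1 in 3 libraries, limma on log2(RPKM + 1) and log2(RPKM + 0.1), replicate number as a block, all 15 libraries in 1 fit, and each library left out. Chosen after seeing the data were the omission of all libraries of a replicate number and of D4h replicate 1, D4h replicates 2 and 3 taken as 1 library, and a block within each kind of RNA. Libraries were taken as paired where the deviations from group means of same-numbered libraries correlated above 0.1 for all 3 numbers. This held for L4h and Dark in total (0.37 to 0.6) and polysome-bound RNA (0.62 to 0.73), and for polysome-bound and total RNA in Dark (0.28 to 0.48) and L4h (0.12 to 0.39), and not for pairs with D4h. Each fit was tested on simulated data with only 200 changed genes, so a larger share can pass where more genes change. Random lists of genes matched on length and expression (10000 lists, 100 neighbors per gene) were drawn for the lists named with them below. Other splits of the libraries were counted, 100 for the interaction.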

Results

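RNA was compared from the aerial part of etiolated Arabidopsis seedlings after 4 days in darkness (Dark), after a further 4 h of white light (L4h) and after a further 4 h of darkness (D4h). Total RNA was sequenced in all 3 conditions and polysome-bound RNA in Dark and L4h, with 3 libraries in each of the 5 groups. Across 22058 genes, the first principal component (43.7% of the variance) parted the L4h libraries from those of dark-kept seedlings, and the second (22.1%) parted polysome-bound from total RNA. The third (13.1%) set replicate 1 of every group apart from replicates 2 and 3. D4h replicate 1 lay between the other D4h libraries and L4h on the first component, with 17500 CPM (read counts scaled to library size) over 21 antenna genes, against 1910 and 1770 CPM in D4h replicates 2 and 3. Those 2 libraries differed from each other by a median of 0.0447 log2 units, with 0.144% of genes over 2-fold apart, where every other pair within a group differed by 0.106 to 0.546. Whether they are separate samples is not known, so D4h tests can rest on 2 samples, and on 1 where D4h replicate 1 is left out. Every p-value measures only the spread between these libraries, and counting intervals and floors cover counting error only.

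**Figure D1:**
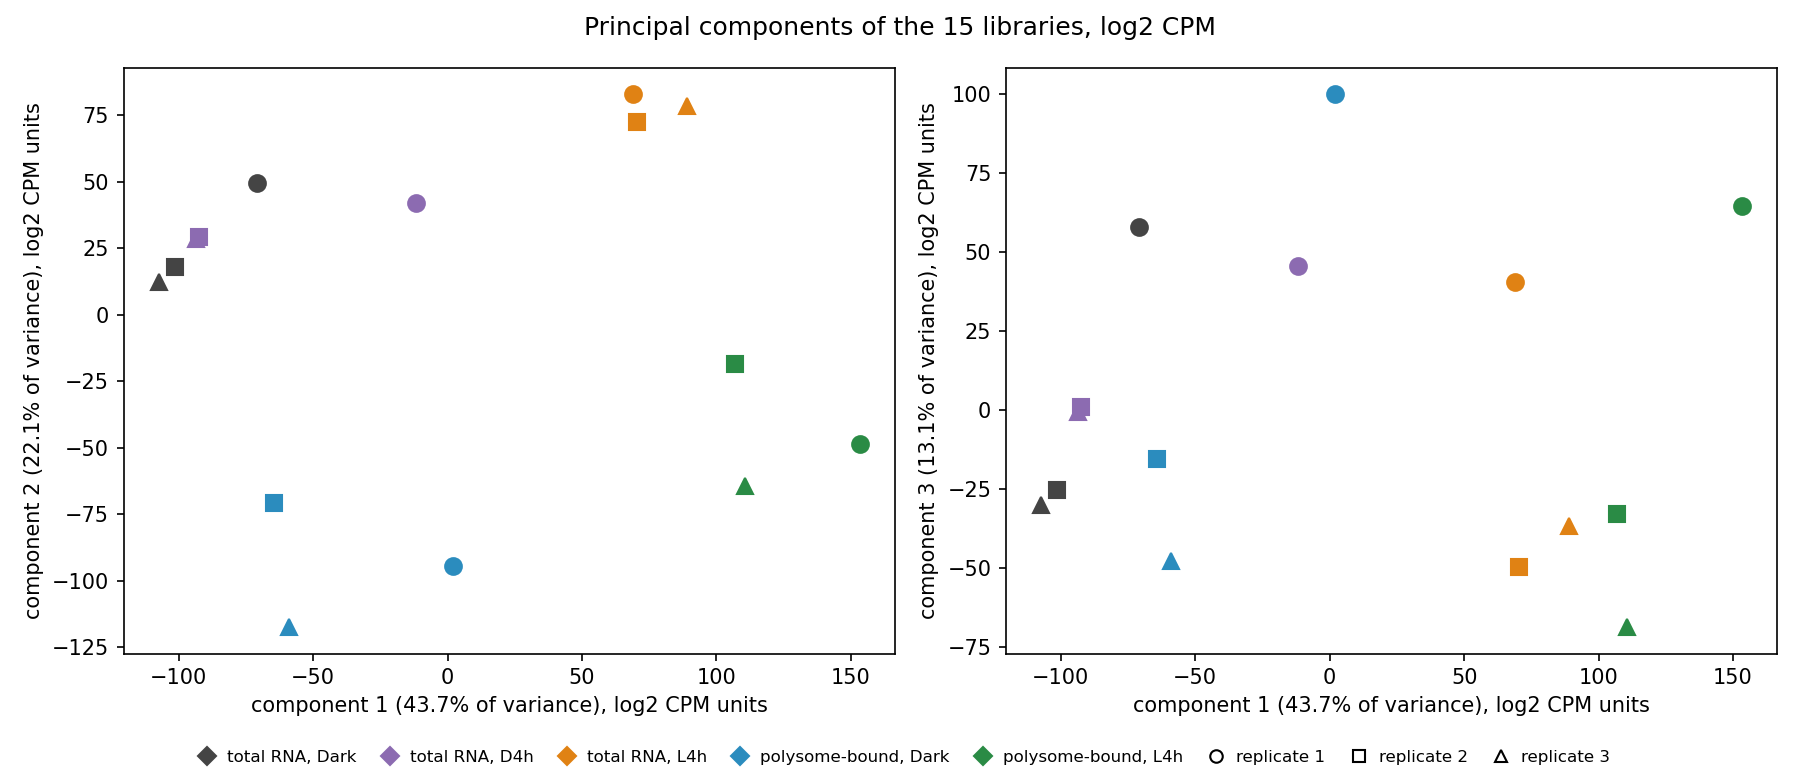
Principal components of log2 CPM in the 15 libraries, with component 2 (left) and component 3 (right) against component 1 on linear axes in log2 CPM units; color gives the group and shape the replicate. L4h libraries lie to the right, polysome-bound libraries lie low on component 2, and replicate 1 lies highest of its group on component 3 (13.1% of the variance).

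Light for 4 h raised mRNAs of photosynthesis, flavonoid synthesis and light-induced regulators in total RNA, and lowered mRNAs of auxin-responsive, cell wall and PIF-activated genes (PIFs are the bHLH factors that promote growth in darkness). Of 21735 genes tested, 2666 rose and 2173 fell in L4h against Dark, 2010 and 1381 of them by at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p, 3 libraries against 3). AT2G15020, an uncharacterized gene, had no read in the Dark libraries and 23.4 ± 11.4 CPM in L4h (mean ± SD), at least 2120-fold more against a floor of 3 counts over the group. The serine carboxypeptidase-like gene scpl10 rose from 0.0192 to 75.9 ± 46.5 CPM (log2 change 12.16 ± 1.2, estimate ± SE, adjusted p = 0.00085). Anthocyanin genes followed: LDOX, encoding anthocyanidin synthase, rose by 9.96 ± 1.5 log2 units to 30.7 ± 24.3 CPM (adjusted p = 0.0044), DFR, encoding dihydroflavonol reductase, by 9.62 ± 1.7 to 18.1 ± 15.3 CPM (0.0075), and the glutathione transferase gene GSTF12 by 9.86 ± 1.8 to 22 ± 17.1 CPM (0.0079). The glycosyltransferase gene UF3GT stood at 13.1 ± 9.72 CPM in L4h and 0.00654 CPM in Dark, where it had 2 reads. With 4 Dark reads for scpl10, 8 for LDOX and 6 each for DFR and GSTF12, the size and rank of these rises are imprecise. The deepest falls were those of the cytochrome P450 gene CYP96A5, from 24.5 ± 9.98 to 0.194 CPM (-6.96 ± 0.66, adjusted p = 0.00068), and the SAUR-like gene AT4G13790 (-6.66 ± 0.55, 5e-04). They were followed by the growth-regulating factor GRF7 (-6.29 ± 0.55, 0.00053), the C2-domain gene AT4G11610 (-6.08 ± 0.58, 0.00069), the F-box gene AT1G20790 (-6.03 ± 0.48, 0.00046) and ACS5, of ethylene synthesis (-5.99 ± 0.59, 8e-04). Reads of scpl10, GSTF12 and GRF7 could not be told apart from those of annotated genes that overlap them, here and below.

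Nuclear genes of the photosynthetic apparatus rose as groups in total RNA of L4h against Dark. Of 21 light-harvesting antenna genes 12 rose and none fell, and 20 rose when adjusted over the list alone (median log2 change 3.57, preset camera test adjusted p = 5.3e-10, adjusted p = 0.38 with an estimated correlation). LHCA1, an antenna protein of photosystem I, rose from 37 ± 35.6 to 1740 ± 510 CPM (log2 change 5.55 ± 1.4, adjusted p = 0.024), and LHCB1.2 of photosystem II from 12.5 ± 8.13 to 1230 ± 592 CPM (6.62 ± 1.6, 0.024), though reads of the near-identical LHCB1 genes cannot be fully told apart. LHCA2 stood at 135 ± 131 CPM in Dark and 846 ± 270 CPM in L4h (adjusted p = 0.094, 0.013 with the replicate block). Of 27 photosystem and electron transport subunits 19 rose, and 27 over the list alone. Their median was 3.2 (adjusted p = 2.5e-11, adjusted p = 0.41 with an estimated correlation). PSAD1 rose from 95.6 ± 83.7 to 694 ± 201 CPM and PSBO2, of the oxygen-evolving complex, from 21.9 ± 19.6 to 517 ± 146 CPM, while PSAD2 passed with the replicate block alone (adjusted p = 0.078, 0.007 with the block). Among 25 genes of chlorophyll and tetrapyrrole synthesis 15 rose and 1 fell, 20 and 1 over the list alone. Their median was 1.92 (adjusted p = 3e-07, adjusted p = 0.44 with an estimated correlation). HEMA1, encoding the glutamyl-tRNA reductase at the entry of the pathway, rose from 77.9 ± 40.3 to 392 ± 133 CPM and GUN4 from 13.1 ± 10.6 to 211 ± 45.2 CPM. The gene that fell was PORA, the protochlorophyllide oxidoreductase of dark-grown seedlings, from 179 ± 30.2 to 4.47 ± 3.38 CPM (-5.32 ± 1, adjusted p = 0.011), and GSA1 did not pass (0.69 ± 0.28, adjusted p = 0.11). In the Calvin cycle 16 of 18 genes rose, 17 over the list alone. Their median was 3.43 (adjusted p = 6.8e-10, adjusted p = 0.38 with an estimated correlation). Among those that rose were RCA, encoding Rubisco activase, from 171 ± 93.9 to 4610 ± 2110 CPM, the Rubisco small subunit gene RBCS1A from 563 ± 225 to 4000 ± 1340 CPM, RBCS1B and the aldolase gene FBA1. Of 30 nuclear genes of plastid ribosomal proteins 11 rose, and 29 over the list alone. Their median was 1.79 (adjusted p = 8.8e-10, adjusted p = 0.43 with an estimated correlation). PRPL10 rose from 25.5 ± 4.98 to 129 ± 40.7 CPM, and PRPS1 (1.84 ± 0.57, adjusted p = 0.051) passed with the block (0.027). Without Dark replicate 2 the adjusted p was 0.089 for LHCA1, 0.09 for LHCB1.2, 0.14 for PSAD1, 0.1 for PSBO2, 0.11 for HEMA1, 0.072 for GUN4, 0.056 for RCA, 0.11 for RBCS1A, 0.052 for RBCS1B and 0.069 for PRPL10.

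Of 17 light-induced transcription factors and regulators 13 rose and 1 fell, 14 and 1 when adjusted over the list alone. Their median was 2.79 (adjusted p = 1.7e-08, adjusted p = 0.28 with an estimated correlation). HY5, a bZIP factor that promotes seedling greening, rose from 13.3 ± 4.7 to 92 ± 15.5 CPM (2.79 ± 0.38, adjusted p = 0.003), its homolog HYH from 0.995 ± 0.897 to 56.4 ± 14 CPM, and the plastid sigma factor SIG5 from 1.73 ± 1.44 to 209 ± 55.5 CPM, while BBX21 fell from 332 ± 25.6 to 142 ± 13.8 CPM. Among 18 photoreceptors, PIFs and repressors of light signalling 9 rose and 1 fell, the same over the list alone. Their median was 0.6 (adjusted p = 0.00048, adjusted p = 0.43 with an estimated correlation). The mRNA of PHYA, the photoreceptor that accumulates in darkness, fell from 1130 ± 505 to 352 ± 108 CPM (-1.68 ± 0.35, adjusted p = 0.013), while PHYB rose from 102 ± 16.1 to 168 ± 5.72 CPM, PIF7 from 0.45 to 17.3 ± 3.83 CPM and SPA1, a partner of the ubiquitin ligase COP1, from 42.3 ± 18.7 to 308 ± 43.1 CPM. In the circadian clock 5 of 19 genes rose and 1 fell, 9 and 1 over the list alone. Their median was 0.7 (adjusted p = 0.022, adjusted p = 0.53 with an estimated correlation). LNK1 rose from 25.1 ± 15.9 to 165 ± 24.8 CPM and BOA fell from 54.2 ± 7.52 to 6.92 ± 3.04 CPM, whereas the morning genes CCA1 (1.68 ± 0.61, adjusted p = 0.082, 0.013 with the block) and LHY (0.39 ± 0.48, 0.6) did not pass. Of 18 phenylpropanoid and flavonoid genes 16 rose, and 18 over the list alone. Their median was 5.64 (adjusted p = 3.2e-11, adjusted p = 0.28 with an estimated correlation). The chalcone synthase gene CHS rose from 3.3 ± 0.745 to 471 ± 276 CPM, and the chalcone isomerase gene CHI from 1.96 ± 0.616 to 52.4 ± 29.1 CPM. Of 19 photoprotection and antioxidant genes 10 rose and none fell, 13 and 1 over the list alone. Their median was 1.64 (adjusted p = 9.3e-06, adjusted p = 0.38 with an estimated correlation). The early light-induced proteins ELIP1 and ELIP2 rose from 1.57 ± 0.288 to 543 ± 376 CPM and from 1.61 ± 0.338 to 200 ± 129 CPM, and PSBS, needed for heat dissipation in photosystem II, from 73.6 ± 31 to 1450 ± 285 CPM. Without Dark replicate 2 the adjusted p was 0.085 for HYH, 0.06 for PHYB, 0.05 for CHS, 0.051 for CHI, 0.068 for ELIP1 and ELIP2 and 0.053 for PSBS, and without L4h replicate 3 it was 0.052 for PHYA.

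Genes of dark growth fell in the same comparison. Of 24 auxin-responsive Aux/IAA, SAUR and GH3 genes 20 fell and 1 rose, 21 and 1 when adjusted over the list alone. Their median was -2.84 (adjusted p = 4.7e-14, adjusted p = 0.28 with an estimated correlation). IAA2 fell from 393 ± 40.7 to 135 ± 56.9 CPM, IAA6 from 38.9 ± 17 to 1.29 ± 0.954 CPM (-4.91 ± 0.6, adjusted p = 0.0019) and SAUR23, which has near-identical copies, from 35.6 ± 11.7 to 1.84 CPM, and SAUR14 was the gene that rose (1.37 ± 0.25, adjusted p = 0.0092). Of 21 expansins and xyloglucan endotransglucosylases, proteins that loosen the cell wall, 11 fell and 3 rose, 12 and 4 over the list alone. Their median was -1.37 (adjusted p = 0.0013, adjusted p = 0.33 with an estimated correlation). XTH19 fell from 264 ± 146 to 12.7 ± 9.32 CPM and EXPA11 from 205 ± 89.8 to 14.8 CPM, EXPA1 rose from 38.4 ± 3.83 to 92.1 ± 37.2 CPM, and EXPA2 did not pass (-0.3 ± 0.39, adjusted p = 0.62). Of 16 PIF-activated shade and dark genes 15 fell, the same over the list alone. Their median was -2.74 (adjusted p = 3.9e-13, adjusted p = 0.0048 with an estimated correlation). The homeobox gene ATHB2 fell from 79.3 ± 3.8 to 7.98 ± 2.16 CPM (-3.31 ± 0.24, adjusted p = 3e-04) and PIL1 from 52.9 ± 15.6 to 6.34 ± 4.65 CPM. Of 15 genes of ethylene synthesis, ethylene signalling and the apical hook 8 fell, and 11 over the list alone. Their median was -1.05 (adjusted p = 9.3e-06, adjusted p = 0.28 with an estimated correlation). HLS1, which keeps the hook closed, fell from 16 ± 6.22 to 3.6 ± 2.08 CPM and ACS8 from 4.75 ± 1.27 to 0.119 CPM, and EIN3 did not pass (-0.84 ± 0.37, adjusted p = 0.13). In 21 gibberellin and brassinosteroid genes 5 rose and 7 fell, 5 and 9 over the list alone. GA2OX1, which inactivates gibberellin, rose from 0.87 to 28 ± 6.44 CPM and GA3OX2 from 0.185 to 8.39 ± 4.41 CPM, and GA20OX1 fell from 16 ± 4.16 to 6.09 CPM. That list had a median of -0.42 and a mean of 0.07, and its test pointed down without passing (adjusted p = 0.43). Without Dark replicate 3 the adjusted p was 0.082 for EXPA1 and 0.054 for PIL1.

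Genes of protein synthesis in the cytosol, of cell division and of reference use moved little in L4h against Dark. Of 34 cytosolic ribosomal protein genes 1 rose and none did when adjusted over the list alone (median 0.18, adjusted p = 0.18). Of 25 cytosolic translation factors 2 rose and none over the list alone (median 0.1, adjusted p = 0.46). Of 17 P-body and mRNA decay genes 2 fell, CAF1A (-1.08 ± 0.21, adjusted p = 0.011) among them, and 1 over the list alone (median -0.09, adjusted p = 0.45). Heat shock and ER chaperones rose in 4 of 14 genes, 7 over the list alone. Their median was 1.35 (adjusted p = 0.00011, adjusted p = 0.38 with an estimated correlation). HSP70-4 rose from 85.4 ± 63.9 to 653 ± 390 CPM and the heat shock factor gene HSFA2 from 1.44 ± 0.34 to 6.96 ± 2.42 CPM, and HSP101 (0.93 ± 0.31, adjusted p = 0.061) passed with the block (0.036). None of 12 seed storage, oleosin and LEA genes passed (median -1.3, adjusted p = 0.091): the cruciferin gene CRA1 ranged from 2.4 to 237 CPM within the Dark libraries. Of 18 genes of fatty acid beta-oxidation and the glyoxylate cycle 2 fell, the same over the list alone. Their median was -0.32 (adjusted p = 0.033, adjusted p = 0.44 with an estimated correlation). The isocitrate lyase gene ICL fell from 942 ± 316 to 229 ± 97.2 CPM, and PCK1, of gluconeogenesis, from 1040 ± 465 to 184 ± 54.5 CPM. Of 13 sugar starvation and dark-inducible genes 2 fell, 5 over the list alone. Their median was -1.6 (adjusted p = 0.00011, adjusted p = 0.43 with an estimated correlation). DIN1 fell from 608 ± 247 to 58.4 ± 65.1 CPM and DRM1 from 793 ± 191 to 209 ± 123 CPM, while ASN1 stood at 1210 ± 1410 and 195 ± 305 CPM (adjusted p = 0.23). In the wound, touch and general stress list 1 of 15 rose, VSP2 (2.4 ± 0.5, adjusted p = 0.014), also over the list alone, with a test that pointed down (median -0.02, mean 0.26, adjusted p = 0.67). No gene passed among 13 cell cycle genes (median 0.43, adjusted p = 0.36) or 10 root markers (median -0.34, adjusted p = 0.31). Of 8 reference genes GAPC2 alone rose (1.55 ± 0.29), also over the list alone, and ACT2 and UBQ10 did not pass (list median -0.07, mean 0.09, test pointing up, adjusted p = 0.83). Without Dark replicate 2 the adjusted p was 0.051 for CAF1A, 0.052 for HSP70-4, 0.065 for DRM1 and 0.061 for VSP2, without Dark replicate 3 it was 0.058 for ICL, and without L4h replicate 2 it was 0.076 for DIN1.

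The groups did not overlap for 43.9% of genes in L4h against Dark, where chance gives 10%. In simulated data at this size, 8%, 64%, 90% and 98% of 2-, 4-, 16- and 64-fold changes were called. Without the libraries numbered 1 the counts were 5240 and 5276, and DESeq2 called 3408 genes lower. Leaving out Dark replicate 2 gave 819 and 862 genes, Dark replicate 3 gave 993 and 971, L4h replicate 2 gave 1639 and 1120, and L4h replicate 3 gave 1446 and 1058. Of 63 genes named here that passed, 37 kept the call whichever library was left out; omitting replicates 1, 2 and 3 ended 1, 24 and 17 of these calls for Dark and 4, 6 and 10 for L4h.

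**Figure D2:**
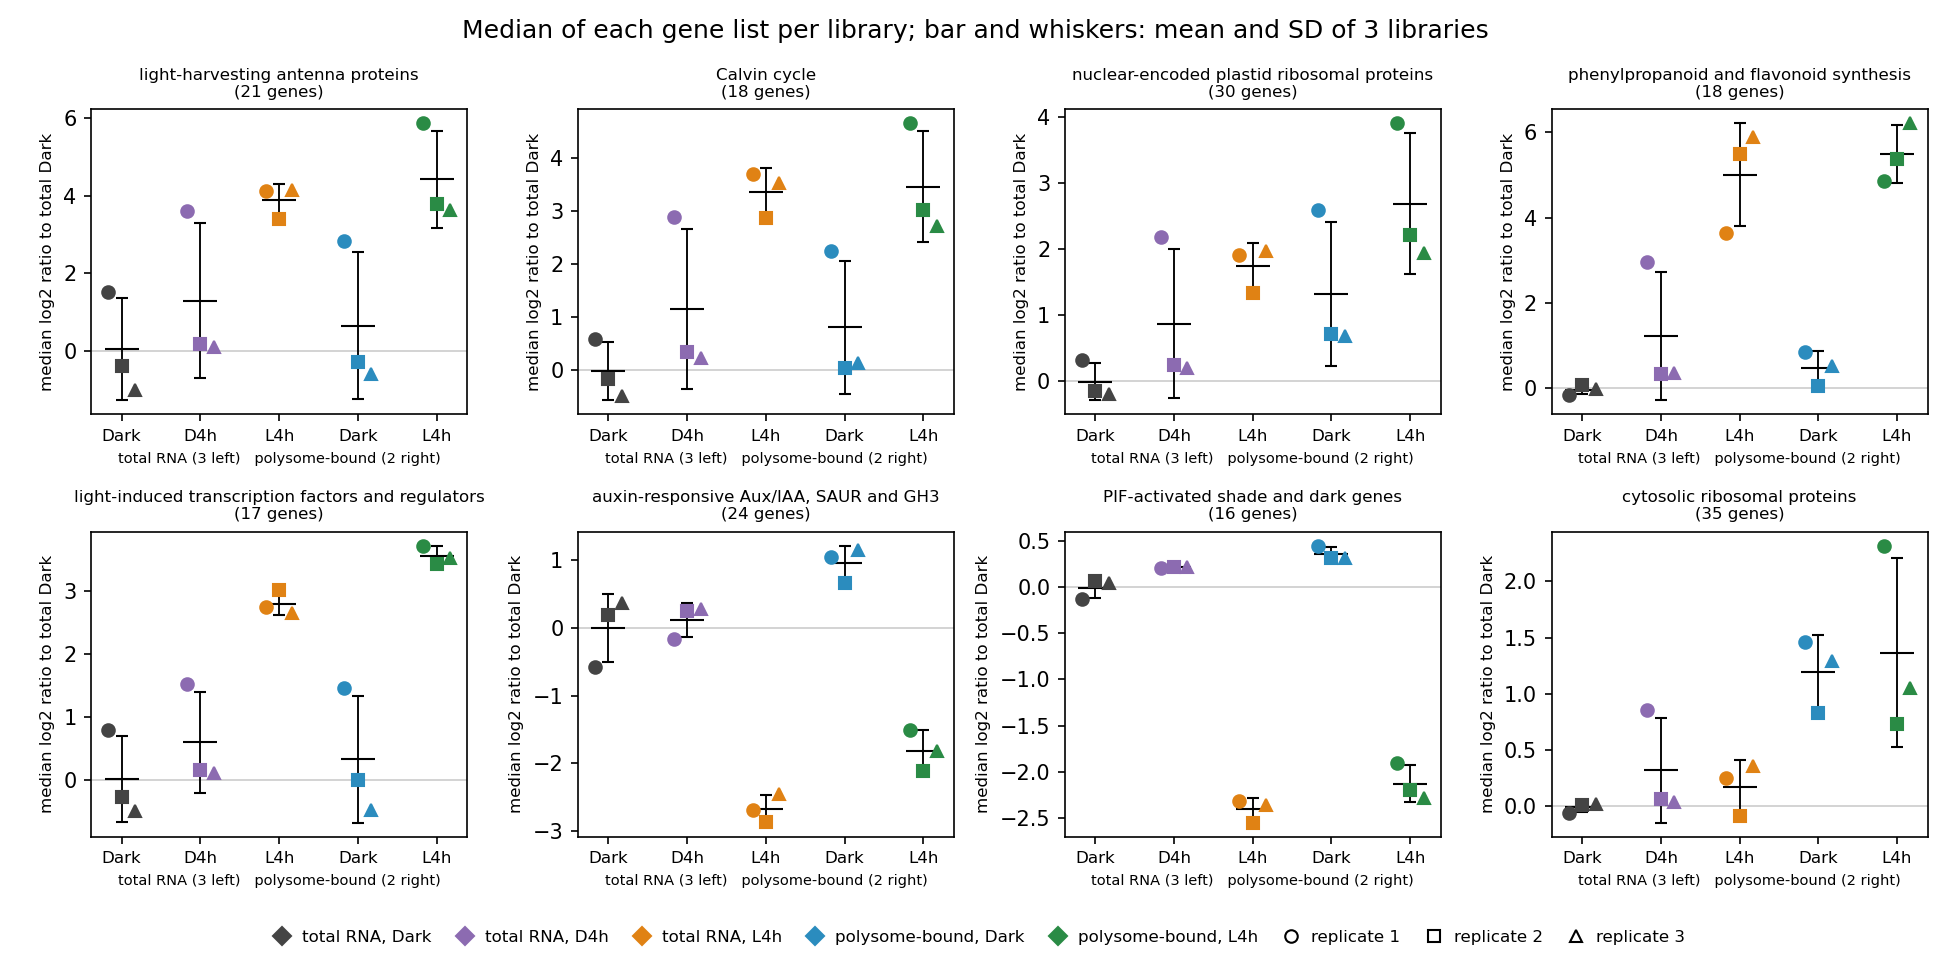
Median log2 ratio to the mean of total RNA in Dark (linear axes) for the genes of 8 lists in each of the 15 libraries, with bar and whiskers giving the mean and SD of 3 libraries. The antenna median in total RNA was 3.61 in D4h replicate 1 and 0.19 and 0.11 in D4h replicates 2 and 3.

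**Figure D3:**
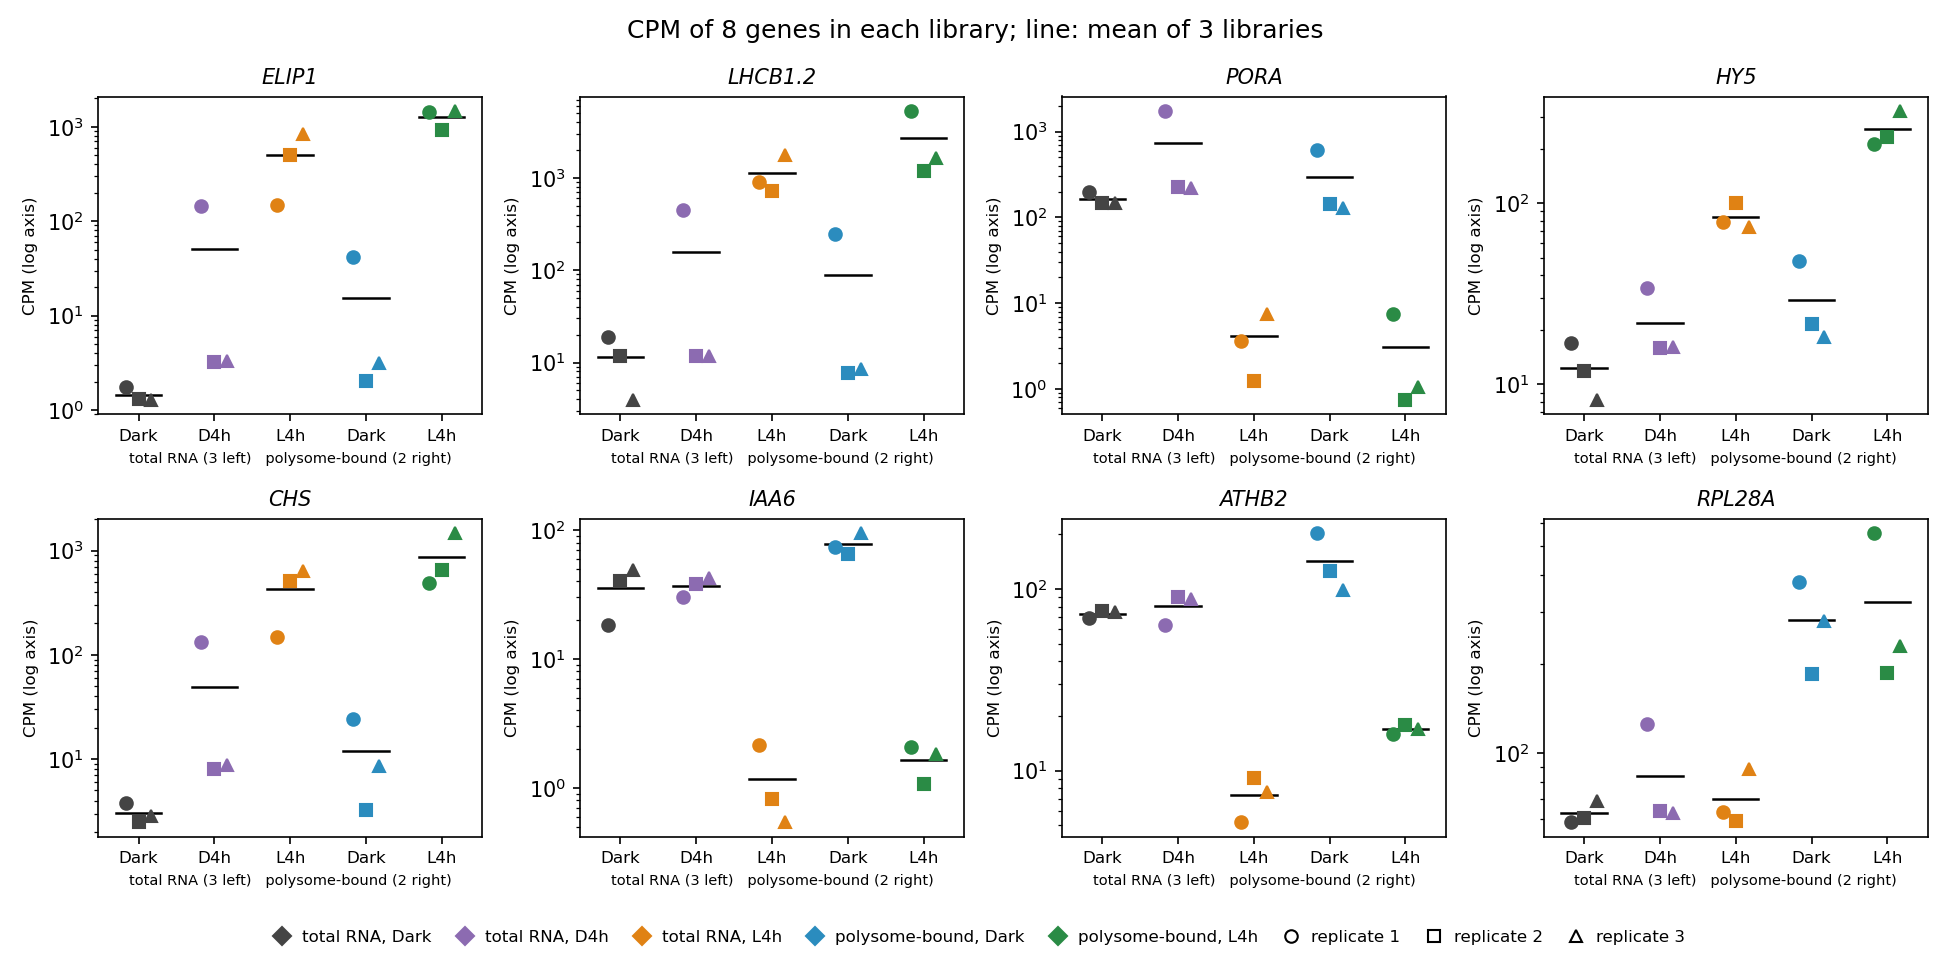
CPM of 8 genes in each library, scaled over all 15 libraries together (log axes), with a line at the mean of 3 libraries. ELIP1, LHCB1.2, HY5 and CHS are higher and PORA, IAA6 and ATHB2 lower in L4h than in Dark, and RPL28A is higher in polysome-bound than in total RNA.

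A further 4 h of darkness left no gene past the threshold in total RNA. In D4h against Dark 0 genes rose and 0 fell of 21735 tested by the edgeR quasi-likelihood test, 794 had an unadjusted p under 0.05, limma called 0, and DESeq2 called 5 higher and 10 lower. The 5 were LHY, ELIP2, CHS, AT3G13700 and AT3G51238, named after their values were seen. D4h replicate 1 differed from its group in genes of greening: LHCB1.3 stood at 7310 CPM there and at 804 and 732 CPM in replicates 2 and 3 and PORA at 1740 against 228 and 219 CPM. List tests, which weigh small shifts of many genes, passed upward for antenna proteins (median 1.7, adjusted p = 4.3e-06), photosystem subunits (1.56, 1.8e-09), chlorophyll synthesis (1.27, 1.1e-09), the Calvin cycle (1.66, 2.5e-08), flavonoid synthesis (1.79, 4.7e-05), photoprotection (0.76, 0.0029) and plastid ribosomal proteins (1.18, 4.3e-12), and with an estimated correlation each had an adjusted p = 0.55. Light-induced regulators (0.65, adjusted p = 0.031), cytosolic ribosomal proteins (0.37, 1.3e-06) and PIF-activated genes (0.22, 0.044) also passed upward, with adjusted p = 0.6, 0.6 and 0.55 with an estimated correlation. Passing downward were heat shock and ER chaperones (-0.8, adjusted p = 0.0057), seed storage, oleosin and LEA genes (-2.67, 5.4e-08), beta-oxidation (-0.24, 0.0021) and wound and stress genes (-0.35, 0.0029), each with adjusted p = 0.55 with an estimated correlation, and sugar starvation genes (-0.44, 0.009; adjusted p = 0.61 with an estimated correlation). Without D4h replicate 1 the medians were -0.26 for antenna proteins, -0.09 for light-induced regulators, 0.04 for cytosolic ribosomal proteins and -0.22 for sugar starvation genes. They were -0.05 for photosystem subunits, 0.14 for chlorophyll synthesis and photoprotection, and 0.18 for the Calvin cycle and plastid ribosomal proteins. Flavonoid synthesis had a median of 0.41, seed storage genes -2.38, auxin response 0.19 and cell wall genes 0.14. This D4h arm can hold a single sample, so only medians are given. Seed storage medians were 0.88, -1.62 and 0.81 in Dark replicates 1 to 3 and -2.69, -1.68 and -1.4 in D4h, so Dark replicate 2 lay at the D4h level. With all libraries the remaining lists, auxin response (median 0.05), cell wall (0.05) and ethylene (-0.06) among them, did not pass (adjusted p from 0.054 to 0.48). Adjusted over the list alone, LHY of the clock list rose and no other gene of any list passed. The groups did not overlap for 12.2% of genes, and simulated 2-, 4-, 16- and 64-fold changes were called in 12%, 74%, 90% and 96% of cases, so 2-fold changes were mostly not detectable.

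Against the dark control of the same age, light again lowered growth genes and raised flavonoid and regulatory genes, and few photosynthesis genes passed. Of 21735 genes 1465 rose and 1586 fell in L4h against D4h, 1060 and 1066 of them by at least 2-fold (edgeR quasi-likelihood test, 3 libraries against 3). The largest rises were those of scpl10, from 0.103 to 75.9 ± 46.5 CPM (log2 change 9.57 ± 1, adjusted p = 0.0011), the beta-glucosidase gene BGLU47 (8.39 ± 1.3, 0.005, imprecise with 10 D4h reads), the thionin gene THI2.2, from 0.281 to 64.9 ± 46.2 CPM (7.89 ± 1.3, 0.0058), AT2G15020 (7.44 ± 1.4, 0.018), the B-box gene BBX32, from 0.134 to 18.8 ± 4.51 CPM (7.14 ± 0.5, 0.00024), and DFR (7 ± 1.4, 0.015). The deepest falls were those of PORA, from 791 ± 956 to 4.47 ± 3.38 CPM (-7.47 ± 1.2, adjusted p = 0.0051), CYP96A5 (-7.08 ± 0.67, 0.00069), GRF7 (-6.94 ± 0.56), AT4G11610 (-6.59 ± 0.6), AT1G20790 (-6.39 ± 0.49) and the EF-hand gene AT2G34020 (-6.3 ± 0.5). BGLU47 and BBX32, like scpl10 and GRF7, overlap other annotated genes. Without D4h replicate 1 the log2 change of PORA was -5.72, less deep than those of the other 5. Without L4h replicate 2 the adjusted p was 0.064 for AT2G15020, and without D4h replicate 3 it was 0.07 for DFR.

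Of the 24 auxin-responsive genes 20 fell and 1 rose in L4h against D4h, 21 and 1 when adjusted over the list alone. Their median was -2.99 (adjusted p = 1.4e-16, adjusted p = 0.25 with an estimated correlation). IAA6 changed from 39.6 ± 6.43 to 1.29 CPM and SAUR23 from 37.6 to 1.84 CPM. Of 16 PIF-activated genes 15 fell, the same over the list alone. Their median was -2.7 (adjusted p = 3.6e-16, adjusted p = 0.0026 with an estimated correlation). ATHB2 changed from 87 ± 15.5 to 7.98 CPM. Cell wall genes fell in 10 and rose in 2 of 21, 11 and 2 over the list alone. Their median was -1.3 (adjusted p = 0.00025, adjusted p = 0.25 with an estimated correlation). XTH19 changed from 288 ± 23 to 12.7 CPM. Ethylene and hook genes fell in 6 of 15, 9 over the list alone. Their median was -0.76 (adjusted p = 2.1e-05, adjusted p = 0.25 with an estimated correlation). HLS1 changed from 20.1 to 3.6 CPM. Flavonoid genes rose in 11 of 18, 17 over the list alone. Their median was 3.14 (adjusted p = 8.3e-10, adjusted p = 0.25 with an estimated correlation). LDOX and CHI passed and CHS did not (54 ± 78 to 471 ± 276 CPM, adjusted p = 0.1), and without D4h replicate 1 the median was 5.27. Light-induced regulators rose in 10 and fell in 1 of 17, 11 and 1 over the list alone. Their median was 2.37 (adjusted p = 3.6e-08, adjusted p = 0.25 with an estimated correlation). HY5 changed from 23.7 ± 11.4 to 92 ± 15.5 CPM and SIG5 from 2.77 ± 3.15 to 209 ± 55.5 CPM, and without D4h replicate 1 the median was 3.01. Photoreceptor and repressor genes rose in 7 and fell in 1 of 18, 9 and 2 over the list alone. Their median was 0.47 (adjusted p = 0.0012, adjusted p = 0.57 with an estimated correlation). PHYA changed from 982 ± 42.2 to 352 ± 108 CPM. In the clock 6 of 19 rose and 2 fell, 7 and 2 over the list alone. Their median was 0.48 (adjusted p = 0.014, adjusted p = 0.6 with an estimated correlation). PRR9 rose from 2.58 to 30.9 ± 7.38 CPM and LHY fell from 119 ± 59.7 to 31.8 ± 14.4 CPM. Heat shock and ER chaperones rose in 10 of 14, 13 over the list alone. Their median was 2.22 (adjusted p = 3.8e-07, adjusted p = 0.25 with an estimated correlation). HSP70-4 changed from 52.8 to 653 ± 390 CPM. In gibberellin and brassinosteroid genes 5 of 21 rose and 6 fell, 6 and 7 over the list alone (median -0.6, mean 0.09, test pointing down, adjusted p = 0.53), with GA2OX1 rising from 0.789 to 28 CPM. Without D4h replicate 2 the adjusted p was 0.052 for LDOX and 0.13 for CHI, without D4h replicate 3 it was 0.053 for HY5, and without L4h replicate 2 it was 0.099 for PHYA and 0.11 for LHY.

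Photosynthesis lists moved with D4h replicate 1, whose antenna sum of 17500 CPM lay 68.8% of the way from the other D4h libraries to the L4h mean. With it, 2 of 21 antenna genes rose in L4h against D4h, LHCB7 and LHCB4.3, the same when adjusted over the list alone. The list median was 1.92 (adjusted p = 1.2e-07, adjusted p = 0.55 with an estimated correlation). LHCA1 did not pass (162 ± 238 to 1740 ± 510 CPM, adjusted p = 0.1). None of 27 photosystem genes passed, also over the list alone. Their median was 1.47 (adjusted p = 1.1e-07, adjusted p = 0.57 with an estimated correlation). Nor did any of 30 plastid ribosomal protein genes pass (median 0.52, adjusted p = 0.00014, adjusted p = 0.71 with an estimated correlation). Chlorophyll synthesis had 2 of 25 genes that fell, PORA and PORB, and 1 over the list alone, against a median of 0.84 (adjusted p = 7e-04, adjusted p = 0.71 with an estimated correlation). In the Calvin cycle 3 of 18 rose, FBA1 and CP12-2 among them, the same over the list alone. The list median was 1.66 (adjusted p = 3.8e-07, adjusted p = 0.55 with an estimated correlation). Of 19 photoprotection genes 4 rose, 6 over the list alone. Their median was 1.02 (adjusted p = 0.00016, adjusted p = 0.51 with an estimated correlation). ABA1 passed and ELIP1 did not (55.3 ± 89.8 to 543 ± 376 CPM, adjusted p = 0.16). Without D4h replicate 1, where the D4h arm can hold a single sample, the list medians were 3.59 for antenna proteins, 3.19 for photosystem subunits and 1.83 for chlorophyll synthesis. They were 3.02 for the Calvin cycle, 1.99 for photoprotection, 1.58 for plastid ribosomal proteins and 0.76 for the clock. Sugar starvation genes fell in 2 of 13, DIN1 and DRM1, the same over the list alone. The list median was -1.16 (adjusted p = 0.0017, adjusted p = 0.57 with an estimated correlation). Beta-oxidation fell in 2 of 18, PCK1 among them, 1 over the list alone (median -0.07, adjusted p = 0.4). A single gene rose in the wound and stress (median 0.13, adjusted p = 0.4) and reference lists (0.06, 0.61), also over the list alone, and 1 of the P-body list fell, none over the list alone (-0.08, 0.61). No gene passed among cytosolic ribosomal proteins (median -0.2, adjusted p = 0.38), translation factors (0, 0.73), seed storage genes (0.97, 0.4), cell cycle genes (0.12, 0.97) or root markers (-0.24, 0.49), nor over the list alone. Without D4h replicate 2 the adjusted p was 0.087 for LHCB7, 0.085 for FBA1 and 0.12 for CP12-2, and without L4h replicate 2 it was 0.14 for PORB, 0.13 for DIN1 and 0.11 for DRM1.

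The groups did not overlap for 35% of genes in L4h against D4h, and simulated 2-, 4-, 16- and 64-fold changes were called in 4%, 56%, 86% and 96% of cases. Without the libraries numbered 1, where D4h can hold a single sample, the counts were 5318 higher and 4940 lower, DESeq2 gave 2658 and 2590, and with D4h replicates 2 and 3 taken as 1 library they were 542 and 725. Leaving out D4h replicate 1 gave 3320 higher, with the same limit, D4h replicate 2 gave 539 and 717, D4h replicate 3 gave 539 and 724, L4h replicate 2 gave 737 and 743, and L4h replicate 3 gave 972 and 915. Of 35 genes named here that passed, 22 kept the call whichever library was left out; omitting replicates 1, 2 and 3 ended 4, 10 and 8 of these calls for L4h and 1, 12 and 11 for D4h.

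In polysome-bound RNA the same groups of genes separated L4h from Dark. Of 20975 genes tested 1124 rose and 1037 fell, 1091 and 989 of them by at least 2-fold, and with replicate number as a block 4584 rose and 4481 fell, among them all 1124 and 1037 (edgeR quasi-likelihood test, 3 libraries against 3). The largest rises were those of AT2G15020, from 0.0337 to 16.2 ± 6.28 CPM (log2 change 8.97 ± 0.72, adjusted p = 0.0019, imprecise with 8 Dark reads), LDOX (8.65 ± 1.1, 0.0065), DFR (7.8 ± 1, 0.0064), the flavanone hydroxylase gene F3H, from 0.583 to 124 ± 58.5 CPM (7.76 ± 0.97, 0.0055), the microRNA precursor MIR163, from 0.119 to 20.3 ± 5.2 CPM (7.46 ± 0.65, 0.0022), and UF3GT (7.42 ± 1, 0.0073). The deepest falls were those of CYP96A5, from 22 ± 5.94 to 0.0893 CPM (-7.99 ± 0.47, adjusted p = 0.0013), the uncharacterized AT5G50175 (-7.78 ± 0.74), GRF7 (-7.08 ± 0.6), AT1G20790 (-7.07 ± 0.4), AT4G11610, from 96.8 ± 3.68 to 0.771 CPM (-6.98 ± 0.39), and PORA, from 263 ± 244 to 2.7 ± 3.3 CPM (-6.62 ± 1.3). F3H and GRF7 overlap annotated non-coding genes. Of 20849 genes tested in both kinds of RNA, 967 rose in both (141 would if independent) and 866 fell in both (105), with 0 in opposite directions and a correlation of 0.93 between the log2 changes across genes. Without polysome L4h replicate 2 the adjusted p of PORA was 0.07.

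Flavonoid genes rose in 13 of 18 in polysome-bound RNA of L4h against Dark, 16 when adjusted over the list alone. Their median was 4.9 (adjusted p = 5.9e-15, adjusted p = 0.23 with an estimated correlation). CHS changed from 10.8 ± 9.76 to 766 ± 474 CPM and CHI from 3.91 to 79.4 ± 32.7 CPM. Light-induced regulators rose in 11 of 17, 14 with 1 falling over the list alone. Their median was 3.02 (adjusted p = 1.7e-10, adjusted p = 0.25 with an estimated correlation). HY5 changed from 26.3 ± 14.8 to 224 ± 55 CPM and SIG5 from 2.54 ± 2.59 to 192 ± 54.9 CPM. Antenna genes rose in 3 of 21, 17 over the list alone and 21 with the block. Their median was 3.28 (adjusted p = 2.6e-11, adjusted p = 0.37 with an estimated correlation). LHCA4 and LHCB7 passed, and LHCA1 stood at 80.9 ± 114 and 2240 ± 1810 CPM (adjusted p = 0.068, 0.00091 with the block). None of 27 photosystem genes passed, also over the list alone, and all 27 did with the block. Their median was 2.63 (adjusted p = 1.1e-10, adjusted p = 0.38 with an estimated correlation). PSAD1 stood at 260 ± 287 and 1300 ± 1120 CPM (adjusted p = 0.18, 0.00059 with the block). Chlorophyll synthesis rose in 4 and fell in 1 of 25, 15 and 2 over the list alone, 22 and 2 with the block. Their median was 1.35 (adjusted p = 1.8e-06, adjusted p = 0.44 with an estimated correlation). HEMA1 changed from 47.6 ± 11.6 to 232 ± 102 CPM and GUN5, a subunit of magnesium chelatase, from 89.2 ± 71.3 to 762 ± 219 CPM. The Calvin cycle rose in 5 of 18, 13 over the list alone and 18 with the block. Their median was 2.55 (adjusted p = 1.9e-08, adjusted p = 0.38 with an estimated correlation). GAPB passed (62.5 ± 55.6 to 681 ± 469 CPM) and RBCS1A did not (adjusted p = 0.28, 0.0016 with the block). No plastid ribosomal protein gene of 30 passed, also over the list alone, and 30 did with the block. Their median was 1.3 (adjusted p = 6.2e-06, adjusted p = 0.5 with an estimated correlation). Photoprotection genes rose in 4 of 19, 5 over the list alone, 15 with 2 falling with the block. Their median was 1.24 (adjusted p = 0.00011, adjusted p = 0.41 with an estimated correlation). ELIP1 changed from 14 ± 20.1 to 1110 ± 265 CPM and PSBS from 108 ± 90.1 to 1190 ± 720 CPM. Photoreceptor and repressor genes rose in 5 and fell in 1 of 18, 6 and 2 over the list alone, 9 and 3 with the block. Their median was 0.44 (adjusted p = 0.028, adjusted p = 0.38 with an estimated correlation). PHYA changed from 649 ± 194 to 180 ± 13.6 CPM. The clock rose in 6 and fell in 1 of 19, 9 and 1 over the list alone, 13 and 2 with the block. Their median was 0.87 (adjusted p = 0.00053, adjusted p = 0.31 with an estimated correlation). LNK1 changed from 12.5 to 105 ± 21.1 CPM. Without polysome Dark replicate 2 the adjusted p was 0.05 for HY5, 0.16 for LHCA4, 0.13 for LHCB7, 0.074 for HEMA1, 0.1 for GUN5, 0.14 for GAPB and 0.11 for PSBS, and without polysome L4h replicate 2 it was 0.076 for ELIP1 and 0.083 for PHYA.

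Auxin-responsive genes fell in 19 of 24 in polysome-bound RNA, 20 with 1 rising when adjusted over the list alone. Their median was -2.6 (adjusted p = 3.2e-16, adjusted p = 0.086 with an estimated correlation). IAA6 changed from 69.9 ± 13.9 to 1.44 CPM, IAA2 from 477 to 162 CPM and SAUR23 from 61.3 ± 18.1 to 3.13 CPM. PIF-activated genes fell in 15 of 16, 16 over the list alone. Their median was -2.72 (adjusted p = 9.8e-15, adjusted p = 0.051 with an estimated correlation). ATHB2 changed from 128 ± 49.1 to 14.8 ± 1.04 CPM. Cell wall genes fell in 9 and rose in 1 of 21, 13 and 2 over the list alone, 14 and 4 with the block. Their median was -1.5 (adjusted p = 9.5e-05, adjusted p = 0.23 with an estimated correlation). XTH19 changed from 244 ± 126 to 8.31 CPM. Ethylene and hook genes fell in 6 of 15, 9 over the list alone and 12 with the block. Their median was -1.01 (adjusted p = 8.3e-08, adjusted p = 0.23 with an estimated correlation). ACS5 changed from 44.9 ± 11.8 to 0.545 CPM. Gibberellin and brassinosteroid genes rose in 2 and fell in 4 of 21, 3 and 6 over the list alone, 7 and 9 with the block (median -0.42, mean 0.08, test pointing down, adjusted p = 0.36), with GA2OX1 rising from 0.668 to 24.6 CPM. Sugar starvation genes fell in 6 of 13, 11 over the list alone. Their median was -1.56 (adjusted p = 4e-07, adjusted p = 0.25 with an estimated correlation). DIN1 changed from 1190 ± 949 to 60.5 CPM and ASN1, asparagine synthetase, from 358 ± 299 to 16.4 CPM. Beta-oxidation fell in 2 of 18, the same over the list alone, 10 with 1 rising with the block. Their median was -0.36 (adjusted p = 0.0048, adjusted p = 0.31 with an estimated correlation). ICL changed from 548 to 130 CPM and PCK1 from 702 to 111 CPM, and the list did not pass without the libraries numbered 1 (0.091). Chaperones rose in 6 of 14, 10 over the list alone and 13 with the block. Their median was 1.87 (adjusted p = 1.5e-07, adjusted p = 0.25 with an estimated correlation). HSP70-4 changed from 59.4 to 445 ± 169 CPM. In the wound and stress list of 15, 2 rose and 1 fell, the same over the list alone (median 0.08, adjusted p = 0.65), LOX2 from no read in Dark to 0.838 CPM, at least 75.5-fold. Among 13 cell cycle genes 1 rose, none over the list alone (median 0.28, adjusted p = 0.2). No gene passed, also over the list alone, among 35 cytosolic ribosomal proteins (median 0.2, adjusted p = 0.45), 25 translation factors (-0.14, 0.61), 17 P-body genes (-0.15, 0.21), 12 seed storage genes (-0.94, 0.32), 10 root markers (-0.45, 0.27) and 8 reference genes (median -0.05, mean 0.04, test pointing up, 0.96). With the block, 1 of these ribosomal protein genes rose, 2 translation factors rose and 3 fell, 5 P-body genes, 5 seed storage genes and 4 root markers fell, and 1 reference gene rose and 1 fell. Without polysome L4h replicate 2 the adjusted p was 0.071 for IAA2, 0.1 for DIN1, 0.15 for ASN1 and 0.14 for ICL, and without polysome Dark replicate 2 it was 0.064 for HSP70-4.

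The groups did not overlap for 30.8% of genes in polysome-bound RNA, and simulated 2-, 4-, 16- and 64-fold changes were called in 4%, 32%, 90% and 96% of cases. Without the libraries numbered 1, 2045 genes were higher, DESeq2 gave 2172 higher and 1863 lower, and 1 fit of all 15 libraries gave 1981 and 1723. Leaving out polysome Dark replicate 2 gave 303 and 408, polysome Dark replicate 3 gave 533 and 569, polysome L4h replicate 2 gave 383 and 338, and polysome L4h replicate 3 gave 646 and 514. Of 38 genes named here that passed, 23 kept the call whichever library was left out; omitting replicates 1, 2 and 3 ended 2, 15 and 8 of these calls for Dark and 8, 12 and 11 for L4h.

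Polysome-bound RNA of Dark seedlings was richer than total RNA in short mRNAs, among them those of photosystem subunits and ribosomal proteins, and poorer in mRNAs of photoreceptors and repressors as a list. Of 21924 genes 2307 were higher and 2034 lower in polysome-bound RNA, 1673 and 1322 of them by at least 2-fold (edgeR quasi-likelihood test, 3 libraries against 3), and 3655 and 3436 with replicate number as a block, among them 2303 and 2032 of the first sets. Cytosolic ribosomal protein genes were higher in 21 of 35, 30 when adjusted over the list alone and 30 with the block. Their median was 1.27 (adjusted p = 6.4e-12, adjusted p = 0.9 with an estimated correlation). RPS6A stood at 97.9 ± 23.8 CPM in total and 335 ± 99.2 CPM in polysome-bound RNA (1.77 ± 0.44, adjusted p = 0.017), RPL28A at 61.1 and 274 ± 93.9 CPM (2.16 ± 0.41, 0.0063), RPL23AA at 76.2 and 332 ± 136 CPM, and RPS6B at 106 and 245 CPM. Plastid ribosomal protein genes were higher in 4 of 30, 19 over the list alone and 24 with the block. Their median was 1.59 (adjusted p = 4.2e-06, adjusted p = 0.93 with an estimated correlation). PRPS17 stood at 28.3 and 212 ± 166 CPM and PRPL18 at 25.3 and 147 ± 143 CPM. Photosystem genes were higher in 2 of 27, PSAE1 and PSBTN, none over the list alone and 19 with the block. The list median was 1.81 (adjusted p = 0.00051, adjusted p = 0.93 with an estimated correlation). Auxin-responsive genes were higher in 7 of 24, the same over the list alone. Their median was 0.82 (adjusted p = 0.00094, adjusted p = 0.9 with an estimated correlation). SAUR21 stood at 29.6 ± 10 and 105 ± 42.2 CPM, and its near-identical copy SAUR20 passed as well. Photoreceptor and repressor genes were lower in 6 of 18, the same over the list alone. Their median was -0.56 (adjusted p = 0.0045, adjusted p = 0.9 with an estimated correlation). PHYB stood at 91.5 and 48.7 CPM, PHYE at 21.8 and 7.11 CPM (-1.61 ± 0.24, adjusted p = 0.0029), and PHYA did not pass (-0.53 ± 0.35, adjusted p = 0.32). Beta-oxidation was lower in 3 of 18, the same over the list alone. Their median was -0.4 (adjusted p = 0.047, 0.051 with the block, adjusted p = 0.9 with an estimated correlation). It did not pass without the libraries numbered 1, 2 or 3 (0.093, 0.055 and 0.069). PXA1, the peroxisomal fatty acid transporter, stood at 115 and 33.3 CPM. Without polysome Dark replicate 1 the adjusted p was 0.17 for PRPL18, 0.28 for PSAE1, 0.15 for PSBTN, 0.082 for SAUR20 and 0.14 for PHYB, without total Dark replicate 1 it was 0.066 for RPS6A and 0.1 for SAUR21, and without total Dark replicate 2 it was 0.076 for RPS6B.

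The genes with the largest polysome to total ratios in Dark were the uncharacterized AT3G22210 (3.84 ± 1.2, adjusted p = 0.045), RBCS1B, at 7.76 and 110 ± 151 CPM (3.83 ± 1.1, 0.029), the thylakoid phosphoprotein gene AT3G47070 (3.79 ± 1, 0.023), AT2G40205 of ribosomal protein L41 (3.77 ± 1.2, 0.047), AT2G01021, at 47.7 ± 26.6 and 640 ± 594 CPM (3.75 ± 0.71, 0.0063), and AT1G21500 (3.46 ± 1.1, 0.041). AT2G01021 lies beside rRNA genes, which took 0.251% to 1.51% of the reads of polysome-bound libraries and 0.08% to 0.238% of those of total RNA. The lowest ratios were those of AT5G28400, at 45.4 ± 4.61 and 1.97 ± 1.24 CPM (-4.52 ± 0.82, adjusted p = 0.0053), the microRNA precursor MIR156f (-4.38 ± 0.99, 0.012), AT3G28945 (-4.1 ± 0.49, 0.0022), the jumonji gene AT1G62310, at 37.3 ± 3.83 and 3.06 ± 1.12 CPM (-3.6 ± 0.3, 0.0019), AT4G02005 (-3.57 ± 0.65, 0.0053) and AT5G28320 (-3.53 ± 0.63, 0.0051). AT5G28400 and AT5G28320 are near-identical copies, and AT3G22210, AT3G47070, AT2G40205, MIR156f, AT1G62310 and AT5G28320 overlap other annotated genes, so their reads are uncertain. Light-induced regulators were higher in 2 of 17, HY5 among them, but none when adjusted over the list alone (median 0.41, adjusted p = 0.24), the clock was higher in 2 and lower in 1 of 19, ELF4 at 5.14 and 16.6 CPM and PRR7 at 83.1 and 23.4 CPM, the same over the list alone (-0.55, 0.23), and translation factors were higher in 5 and lower in 1 of 25, 5 and 2 over the list alone (0.34, 0.21), with EIF5A-2 at 419 and 1100 ± 242 CPM. P-body genes were higher in 2 and lower in 2 of 17, 2 and 3 over the list alone (median -0.09, mean 0, test pointing down, adjusted p = 0.82), XRN4, a cytosolic exonuclease, at 84.6 and 41 CPM. Photoprotection was higher in 2 of 19, 6 with 1 lower over the list alone (median 0.83, adjusted p = 0.13, 0.024 without the libraries numbered 3). A single gene was higher among antenna proteins, the Calvin cycle (RBCS1B), PIF-activated (ATHB2), gibberellin and brassinosteroid and cell cycle genes, and a single root marker was lower. Of these, that of the cell cycle list alone passed over the list alone, and none of the 6 list tests passed (adjusted p from 0.06, for the Calvin cycle, with 0.0055 in the block fit and 0.02, 0.01 and 0.022 without the libraries numbered 1, 2 and 3, to 0.97). Reference genes were higher in 3 and lower in 1 of 8, also over the list alone (median 0.35, adjusted p = 0.25), EXPRS among the higher. None passed, also over the list alone, among chlorophyll synthesis, flavonoid, cell wall, ethylene, chaperone, seed storage, sugar starvation and wound and stress genes (adjusted p from 0.34 to 0.84). Without polysome Dark replicate 1 the adjusted p was 0.34 for AT3G22210, 0.17 for RBCS1B, 0.11 for AT3G47070, 0.2 for AT2G40205, 0.3 for AT1G21500, 0.16 for HY5 and 0.098 for ATHB2.

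The groups did not overlap for 41.7% of genes between polysome-bound and total RNA in Dark, and simulated 2-, 4-, 16- and 64-fold changes were called in 4%, 56%, 88% and 98% of cases. The balance of higher and lower genes differed between settings: 53.1% of called genes were higher with TMM scaling, 52.6% with RLE, and, with test and scaling both changed, 36% with limma on log2(RPKM + 1) (1558 higher and 2775 lower) and 37.1% on log2(RPKM + 0.1) (1489 and 2526), where the median of all genes was -0.14 and -0.23 (0 with TMM). Leaving out total Dark replicate 1 gave 1415 and 1184, total Dark replicate 2 gave 1226 and 1007, total Dark replicate 3 gave 1364 and 1195, polysome Dark replicate 1 gave 1481 and 1210, and polysome Dark replicate 3 gave 1051 lower. Of 32 genes named here that passed, 17 kept the call whichever library was left out; omitting replicates 1, 2 and 3 ended 14, 15 and 13 of these calls for total and 15, 1 and 3 for polysome-bound RNA.

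In L4h the contrast of polysome-bound with total RNA had much the same members. Of 21924 genes 2546 were higher and 1985 lower in polysome-bound RNA, 1821 and 1205 of them by at least 2-fold (edgeR quasi-likelihood test, 3 libraries against 3), and 3845 and 3344 with replicate number as a block, among them 2543 and 1982 of the first sets. Between the Dark and L4h contrasts, which share no library, 1999 higher genes (268 if independent) and 1561 lower genes (184) were common, 0 were opposite, and the log2 ratios correlated at 0.83 across genes. Cytosolic ribosomal protein genes were higher in 27 of 35, 29 when adjusted over the list alone. Their median was 1.44 (adjusted p = 4.8e-11, adjusted p = 0.9 with an estimated correlation). RPS6A stood at 126 and 400 ± 253 CPM, RPL28A at 68.4 and 315 ± 195 CPM and RPL23AA at 94 and 419 ± 324 CPM. Auxin-responsive genes were higher in 9 of 24, 11 over the list alone. Their median was 0.94 (adjusted p = 0.00052, adjusted p = 0.9 with an estimated correlation). SAUR21 stood at 2.18 and 7.98 CPM. Photoreceptor and repressor genes were lower in 5 of 18, 6 over the list alone. Their median was -0.67 (adjusted p = 0.00052, adjusted p = 0.9 with an estimated correlation). PHYE stood at 35.9 and 11.6 CPM and PHYB at 150 and 85.6 CPM (adjusted p = 0.062, 0.033 with the block). Beta-oxidation was lower in 3 of 18, also over the list alone. Their median was -0.45 (adjusted p = 0.015, adjusted p = 0.9 with an estimated correlation). It did not pass without the libraries numbered 1 (0.097). PXA1 stood at 103 and 32.3 CPM. Plastid ribosomal protein genes were higher in 1 of 30, PRPS17, none over the list alone and 6 with the block. Their median was 1.16 (adjusted p = 0.0024, adjusted p = 0.9 with an estimated correlation). Of 27 photosystem genes none passed, also over the list alone, and 6 did with the block. Their median was 1.38 (adjusted p = 0.016, adjusted p = 0.9 with an estimated correlation). HY5 stood at 82.1 ± 13.8 CPM in total and 249 ± 57.7 CPM in polysome-bound RNA (1.6 ± 0.38, adjusted p = 0.015), ELF4 at 33.4 and 122 CPM and PRR7 at 114 and 38.2 CPM. Without polysome L4h replicate 1 the adjusted p was 0.13 for SAUR21 and 0.097 for PRPS17, without total L4h replicate 2 it was 0.083 for RPS6A, without total L4h replicate 3 it was 0.06 for HY5, and without polysome L4h replicate 3 it was 0.057 for PRR7.

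The largest ratios in L4h were those of the RNA-binding protein gene ATRZ-1A (3.57 ± 0.46, adjusted p = 0.0021), AT4G31985 of ribosomal protein L39, at 19.8 and 195 ± 172 CPM (3.3 ± 0.69, 0.008), AT3G10860 of the mitochondrial cytochrome complex, at 40.9 and 314 ± 125 CPM (2.94 ± 0.4, 0.0021), the uncharacterized AT2G20835 (2.94 ± 0.73, 0.017), AT2G47115 (2.93 ± 0.59, 0.0072) and AT4G33865 of ribosomal protein S29 (2.92 ± 0.79, 0.024). The lowest were those of AT5G28400 (-4.52 ± 0.83, adjusted p = 0.0047), the non-coding RNAs AT5G15845 (-3.68 ± 0.83, 0.011) and AT5G26146 (-3.49 ± 0.92, 0.022), AT1G62310, at 20.7 and 1.8 CPM (-3.52 ± 0.3, 0.0016), AT5G28320 (-3.41 ± 0.63, 0.005) and AT1G53785 (-3.12 ± 0.33, 0.0018). ATRZ-1A, AT3G10860, AT5G15845, AT5G26146, AT1G62310 and AT5G28320 overlap other annotated genes. Light-induced regulators were higher in 2 and lower in 1 of 17, also when adjusted over the list alone (median 0.45, adjusted p = 0.36), the clock higher in 2 and lower in 1 of 19, also over the list alone (-0.33, 0.62), and translation factors higher in 5 and lower in 4 of 25, also over the list alone (0.23, 0.57), EIF5A-2 at 446 and 1100 ± 174 CPM. P-body genes were higher in 2 and lower in 4 of 17, also over the list alone (median -0.03, adjusted p = 0.57), AGO1, the main slicer of small RNA pathways, at 229 and 100 CPM. Photoprotection was higher in 1 and lower in 1 of 19 and antenna proteins, the Calvin cycle and chaperones were higher in 1 gene each, none of them over the list alone (adjusted p from 0.41 to 0.57). PIF-activated genes were higher in 2 and lower in 1, seed storage, wound and stress (ZAT12) and cell cycle genes higher in 1 each, and reference genes higher in 3 and lower in 1, the same over the list alone (adjusted p from 0.19 to 0.43). None passed, also over the list alone, among chlorophyll synthesis, flavonoid, cell wall, ethylene, gibberellin and brassinosteroid, sugar starvation and root marker genes (adjusted p from 0.33 to 0.9). On an omission alone, chlorophyll synthesis (-0.64, adjusted p = 0.00048) and wound and stress genes (0.6, 0.043) passed without the libraries numbered 1, seed storage genes (1.17, 0.024) without number 2, and sugar starvation (-0.77, 0.043) and cell cycle genes (0.64, 0.034) without number 3. Without polysome L4h replicate 1 the adjusted p was 0.072 for AT2G20835 and 0.11 for AT4G33865, without total L4h replicate 1 it was 0.082 for AT5G26146, and without polysome L4h replicate 3 it was 0.065 for AGO1.

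The groups did not overlap for 40.5% of genes between polysome-bound and total RNA in L4h, and simulated 2-, 4-, 16- and 64-fold changes were called in 6%, 56%, 88% and 92% of cases. Of called genes 56.2% were higher with TMM scaling, 54.3% with RLE, 33.3% with limma on log2(RPKM + 1) (1621 higher and 3252 lower) and 34.1% on log2(RPKM + 0.1) (1555 and 3001), where the median of all genes was -0.16 and -0.26 (0.02 with TMM). On log2(RPKM + 0.1) list medians turned sign for the Calvin cycle (0.35 to -0.16), translation factors (0.23 to -0.11) and chaperones (0.32 to -0.19), among others. Leaving out total L4h replicate 1 gave 1292 lower, total L4h replicate 2 gave 1395 and 1053, total L4h replicate 3 gave 1471 higher, polysome L4h replicate 1 gave 1602 higher, and polysome L4h replicate 3 gave 1680 and 1226. Of 25 genes named here that passed, 16 kept the call whichever library was left out; omitting total RNA replicates 1, 2 and 3 ended 6 calls each, and omitting polysome replicates 1, 2 and 3 ended 6, 0 and 4.

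**Figure D4:**
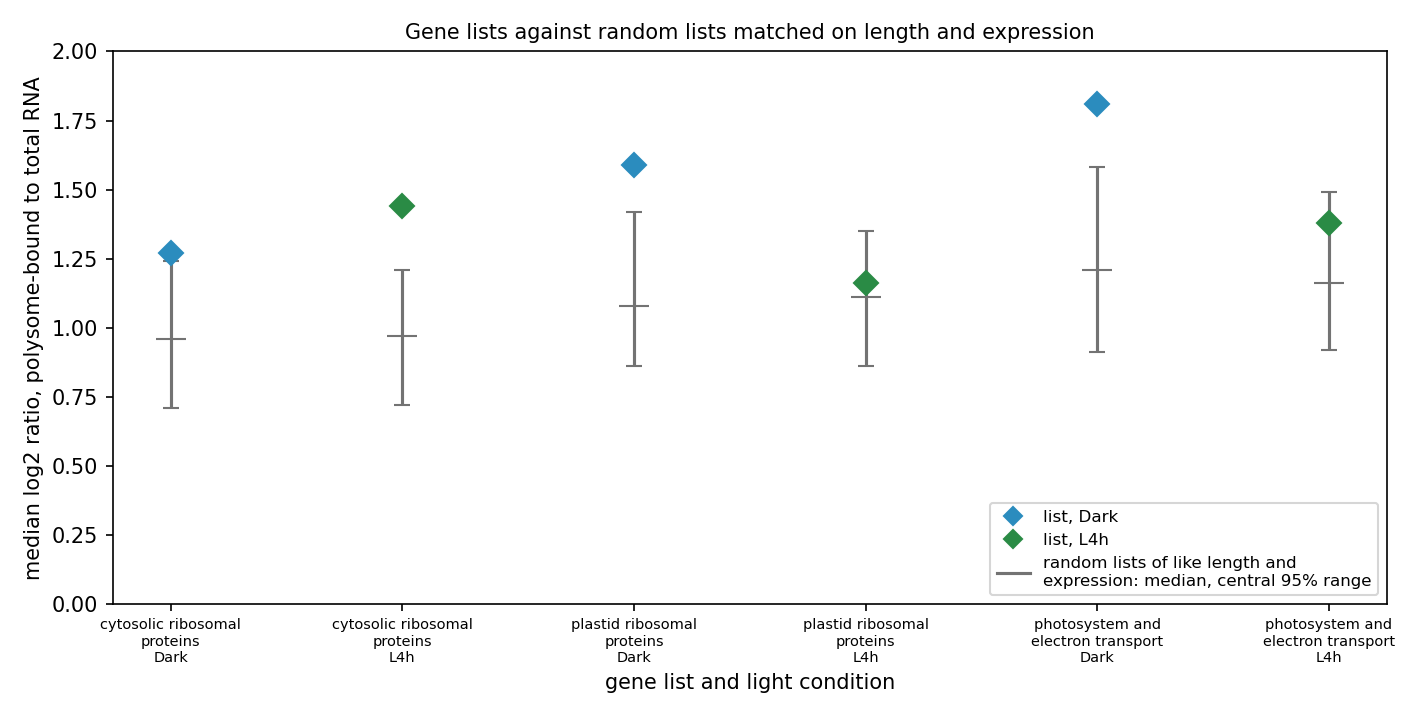
Median log2 ratio of polysome-bound to total RNA (linear axis) for 3 gene lists in Dark and L4h (diamonds), beside the median and the central 95% range of 10000 random lists of genes with like length and expression (gray). Cytosolic ribosomal proteins lay above that range in both conditions (1.27 and 1.44), the other lists in Dark (1.59 and 1.81) but not in L4h (1.16 and 1.38).

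In the test of whether the light effect differed between polysome-bound and total RNA, and with it polysome association, 0 of 21924 genes were higher and 0 lower by the edgeR quasi-likelihood test, with or without the replicate block, 114 had an unadjusted p under 0.05, DESeq2 called 2 higher and 1 lower, and limma on log2(RPKM + 0.1) called 1 higher. Those genes were EXO70H6 and AT2G23672 (higher) and RBL5 (lower) with DESeq2 and PTAC18 with limma, named after their values were seen. HY5 differed by 0.35 ± 0.53, RPS6A by -0.11 ± 0.6, LHCA1 by -0.7 ± 1.4 and ATHB2 by 0.25 ± 0.38 log2 units (each adjusted p = 1). List tests passed downward, meaning a lower light effect in polysome-bound than in total RNA, for chlorophyll synthesis (median -0.49, 23 of 25 genes negative, adjusted p = 6.6e-07), plastid ribosomal proteins (-0.44, 27 of 30, 3e-04), the Calvin cycle (-0.78, 16 of 18, 5e-04), photosystem subunits (-0.51, 24 of 27, 0.021), photoprotection (-0.43, 17 of 19, 0.024) and translation factors (-0.16, 16 of 25, 0.042, 0.053 with the block). They passed upward for chaperones (0.48, 12 of 14 positive, adjusted p = 0.013), wound and stress genes (0.26, 12 of 15, 0.025) and the clock (0.25, 16 of 19, 0.033, 0.053 with the block). With an estimated correlation photosystem subunits had an adjusted p = 0.85 and each of the other 8 lists an adjusted p = 0.79. The remaining lists did not pass (adjusted p from 0.11 to 0.94), among them antenna proteins (median -0.27), flavonoid synthesis (-0.44), auxin response (0.06), PIF-activated genes (-0.1) and cytosolic ribosomal proteins (0.04, test pointing down). Without the libraries numbered 3, none of the 9 lists passed (adjusted p from 0.088, for the Calvin cycle, to 0.8, for translation factors). List tests on omissions used z-scores of the counts, so they differ from the tests above in statistic too. On an omission alone, cytosolic ribosomal proteins passed upward without the libraries numbered 3 (0.36, 0.0012) and downward without number 1 (-0.32, 6.4e-05), antenna proteins (0.00041 and 0.037) and flavonoid synthesis (0.046 and 0.018) downward and seed storage genes upward (0.0089 and 1.1e-08) without numbers 1 and 2, auxin response upward without number 1 (0.0025), and, without number 3, cell wall (0.04) and sugar starvation genes (0.028) downward and cell cycle genes upward (0.031). No gene of any list passed when adjusted over the list alone. Simulated 2-, 4-, 16- and 64-fold differences were called in 0%, 32%, 84% and 94% of cases, so 2-fold differences were not detectable. Leaving out polysome Dark replicate 1 gave 1 gene higher (MYB106), leaving out polysome L4h replicate 3 gave 1 lower (SAE1B), and without the libraries numbered 1 PIA1 was higher and AT3G13700 lower, all named after their values were seen.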

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

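Tests of D4h replicate 1, of the non-coding RNAs, of the omission of libraries numbered 1 or 3 and of other splits of the samples were chosen after the results were seen. Marked for a closer look were 9 gene lists whose light effect differed between polysome-bound and total RNA in the preset camera test (adjusted p): chlorophyll synthesis 6.6e-07, plastid ribosomal proteins 3e-04, Calvin cycle 5e-04, heat shock and ER chaperones 0.013, photosystem subunits 0.021, photoprotection 0.024, wound and stress genes 0.025, clock 0.033 and translation factors 0.042. With an estimated correlation none passed (adjusted p = 0.79 to 0.85).

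In the chlorophyll, plastid ribosomal protein and Calvin cycle lists the light effect was lower in polysome-bound than in total RNA (medians -0.49, -0.44 and -0.78), with medians of -0.21, -0.36 and -0.67 in replicate 1, -0.23, -0.04 and -0.09 in replicate 2 and -1.1, -0.98 and -1.25 in replicate 3. The medians lay -0.47, -0.42 and -0.71 beyond those of matched random lists, and 0 of 10000 lists were as low. Gene length and expression level do not account for the first 2, and in the Calvin cycle expression, not fully matched (8.87 against 7.94 log2 CPM), cannot be told apart. Without the libraries numbered 3 the medians were -0.19, -0.26 and -0.53 and the lists no longer passed (adjusted p = 0.11, 0.22 and 0.088), so these libraries may carry much of the shift in chlorophyll synthesis. In the other 2 lists, where most of the shift stayed, this cannot be told apart. Whether polysome association itself changed with light stays open.

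Cytosolic ribosomal protein, plastid ribosomal protein and photosystem mRNAs were higher in polysome-bound than in total RNA, and across 21070 coding genes the ratio fell with gene length (Spearman rho -0.62 in Dark and -0.7 in L4h). Length and expression do not account for the whole excess of cytosolic ribosomal proteins in Dark, 0.31 log2 over matched lists and 0.37 without the libraries numbered 1. The excess of cytosolic ribosomal proteins in L4h (0.47) and of plastid ribosomal proteins (0.51) and photosystem subunits in Dark (0.61, with expression not fully matched and so not told apart) went to 0.16, -0.07 and 0.09 without the libraries numbered 1, within the range of matched lists, so these libraries may carry it. The medians of plastid ribosomal proteins and photosystem subunits then fell from 1.59 to 0.81 and from 1.81 to 1.07 in Dark, and from 1.16 to 0.37 and from 1.38 to 0.38 in L4h. In L4h plastid ribosomal proteins (0.05 over matched lists, 35.2% of them as high) and photosystem subunits (0.22, 8.55%) lay within the range of matched lists, but below it without the libraries numbered 1 (-0.56 and -0.65), so length and expression cannot be told apart there. Whether the length trend is technical or biological was not tested.

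D4h replicate 1 had antenna mRNAs at 17500 CPM, against 1910 and 1770 CPM in its group. An exchange for a light-treated library is argued against by its PIF and auxin genes, which summed to 2890 CPM, above the 1220 to 1380 CPM of the L4h libraries. A mixture with an L4h library, which would bring all light-raised genes in 1 share, is also argued against. Of 235 other genes at least 4-fold higher in L4h than in the other dark libraries, at least 41.3% held under 0.5 of the share that the antenna genes need (0% in mixtures computed from the libraries). A difference that goes with replicate number 1 cannot be told apart. Replicate 1 had the highest antenna median in 3 of 4 other groups, too few to decide (polysome Dark: 2.83 against -0.27 and -0.58). In total L4h it had 4.12 and replicate 3 had 4.14. No biological explanation was tested.

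With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 4839 genes for L4h against Dark in total RNA (highest other 0), 3051 for L4h against D4h (1), 2161 for polysome-bound RNA (0), and 4341 and 4531 for polysome-bound against total RNA in Dark (1) and L4h (0), with 1 split as large in each, the real one. For D4h against Dark, with 0 genes, all 10 splits were as large (highest other 1). For the interaction, with 0 genes, 100 of 100 splits were as large, which a count of 0 fixes in advance. The highest, 7347 genes, exchanged the light and dark labels of total RNA, a structure of the samples that adds up the light responses of both kinds of RNA.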

How the results depend on the processing

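Settings chosen after seeing the data are named above. Counts are higher / lower genes, and the cause of each move was not tested. RLE scaling, both filters and the block within each kind of RNA moved no count by over 1.5 times. DESeq2 gave 3408 lower for L4h against Dark in total RNA, 5 / 10 for D4h against Dark, 2658 / 2590 for L4h against D4h, 2172 / 1863 for light in polysome-bound RNA and 2 / 1 for the interaction. Without all libraries numbered 1 the counts were 5240 / 5276 for L4h against Dark, 5318 / 4940 for L4h against D4h, 2045 higher in polysome-bound RNA and 1 / 1 for the interaction. With D4h replicates 2 and 3 as 1 library, L4h against D4h gave 542 / 725 and D4h against Dark 0 / 0, and 1 fit of all 15 libraries gave 1981 / 1723 in polysome-bound RNA. limma on log2(RPKM + 0.1) gave 1489 higher for polysome-bound against total RNA in Dark, 1555 / 3001 in L4h and 1 higher for the interaction, and limma on log2(RPKM + 1) gave 1621 / 3252 in L4h.

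The replicate block gave 4584 / 4481 for light in polysome-bound RNA and 3655 / 3436 and 3845 / 3344 for polysome-bound against total RNA in Dark and L4h, and, beyond the genes and lists for which the block value is printed, changed no other call of a list or named gene in these paired comparisons. D4h shares only numbers with the other groups (correlations 0.08 to 0.15 with Dark and -0.27 to 0.31 with L4h). There the block gave 0 / 0 for D4h against Dark, with PIF-activated genes at adjusted p = 0.078, and 2256 higher for L4h against D4h, where DFR, LHY and PORB no longer passed (adjusted p = 0.057, 0.07 and 0.065) and LHCA1 did (0.015).

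Leaving out 1 library gave 819 to 2448 / 862 to 2113 for L4h against Dark, 0 / 0 for D4h against Dark, 539 to 3320 / 717 to 2195 for L4h against D4h, 303 to 1520 / 338 to 1074 in polysome-bound RNA, 1226 to 2343 / 1007 to 1959 and 1395 to 2268 / 1053 to 1948 for polysome-bound against total RNA in Dark and L4h, and 0 to 1 / 0 to 1 for the interaction. Of 214 named gene results 120 stayed on the same side of the threshold in every setting, 78 lost the call in some and 0 turned direction, and DESeq2, which gave an adjusted p for 204, ended none of these. Of 86 list calls the estimated correlation ended 84 and the block 4. The omission of a replicate number was run on the 38 list calls in polysome-bound RNA, polysome-bound against total RNA and the interaction. It reversed 1, translation factors in the interaction without libraries numbered 3 (adjusted p = 0.8), and ended 3 calls without libraries numbered 1 (all beta-oxidation), 2 without those numbered 2 (beta-oxidation, and translation factors in the interaction) and 9 without those numbered 3. Leaving out organelle genes was not run, as none is listed. At 60.8 to 100.9 M reads, depth limits genes with few reads: scpl10 rested on 4 Dark reads, LDOX on 8 and DFR on 6.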

Other observations

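Non-coding RNAs, tested after the results were seen, were poorer in polysome-bound than in total RNA. In Dark 0 of 49 microRNA precursors were higher and 22 lower (median -2.01), 8 and 35 of 151 long non-coding RNAs (-0.79), and 0 and 19 of 27 small nucleolar RNAs (-2.29), against 2282 and 1814 of 21070 coding genes (0.02). In L4h the counts were 1 and 17 (-1.95), 5 and 26 (-0.68), and 0 and 16 (-2.17). The tables argue against gene length and expression level as the cause: medians lay beyond those of matched coding genes by -2.43 and -2.5 for microRNA precursors, -0.76 and -0.71 for long non-coding RNAs and -2.84 and -2.78 for small nucleolar RNAs (Dark and L4h). The matched coding genes were longer (0.381 against 0.149 kb and 0.357 against 0.086 kb), and capture of poly(A) or size selection in the library was not tested.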
